A study of Mus musculus with 8 samples.

How the data were processed

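The series measured messenger RNA on Affymetrix whole-transcript arrays in mouse CD4 T cells. Naive cells came by sorting from mice with intact Bcl6 (wild type, WT) and from mice lacking Bcl6 in T cells (KO), and were cultured for 24 hours with antibodies to CD3 and CD28, with antibodies that block IL-4, interferon gamma and TGF beta, and with the cytokines IL-6 and IL-21, per the labels' protocols. RNA was isolated on Qiagen RNeasy columns, and 100 ng of total RNA per sample was labelled with biotin, per the labels' protocols. There were 4 arrays of each genotype, and each group was taken from the sample titles. The labels do not say whether the 4 arrays of a group came from separate mice, so the p-values measure the spread between these samples, which may be partly technical.

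The authors deposited 1 value per probe set and array on the log2 scale, rounded to 2 decimals, and per the submitters' processing notes the tools were RMA and Partek. No version, order of steps or annotation release is given in the sources used here. The standard steps of RMA are background correction, quantile normalization and a summary over probes, so the arrays enter with nearly equal distributions and a change in total RNA per cell cannot be seen. The median over 35556 probe sets lay between 7.35 and 7.42 in all 8 arrays. The number of arrays limits the precision.

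Probe sets were named through the platform annotation table. It gave 1 gene symbol for 21789 probe sets and several for 1621, and 12146 probe sets were not listed there and are unnamed here. Of the probe sets with 1 symbol, 21698 matched the RefSeq mouse gene table by Entrez identifier, and no symbol needed updating. No gene was named from a probe set with several symbols. Of the 19938 genes left, 999 had more than 1 probe set, and the probe set with the highest mean over the 8 arrays stood for the gene. Genes entered the test where the value lay above the 40th percentile of the array in at least 4 arrays, and Bcl6 was kept whatever its level, which left 11926 genes. The files name no genome build, so the gene table (assembly GRCm38.p6) was used for names and for the order of genes along chromosomes, and no coordinates are given.

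KO-labelled and WT-labelled arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are KO minus WT on the log2 scale. Single genes also received an exact permutation test of 4 against 4 values, whose smallest possible two-sided p is 0.0286. Of 26 gene lists fixed before the data were examined, 21 had at least 5 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The B cell, myeloid and erythroid lists had fewer members and are given as counts, the sex-linked genes served as a check of the samples, and the mitochondrially encoded list had no named probe set. Counts of list members adjusted over the list alone are given beside the counts over all genes. Genes near Bcl6 were compared with the others by Fisher's exact test on the 10 nearest tested genes on either side.

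The genes named were fixed by rule before the data were examined. The rule took Bcl6, 16 regulators and receptors of T helper cells, the 10 largest rises and 10 largest falls among genes past the threshold with no overlap between the groups, and, for each list, up to 2 members with the largest rise and 2 with the largest fall, or else the member with the smallest p. Predicted genes, clones, microRNAs, small nucleolar RNAs and antigen-receptor segments were counted but left out of the largest rises and falls. Of these 16, 1 is not reported here.

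The steps were tested on simulated data made from the arrays' own means and spreads, in 20 simulations of 11926 genes with 200 changed genes each. The test recovered 85.5% of genes changed by 0.5 and 98.6% of those changed by 1 on the log2 scale, and 4.71% of its calls were false. With no gene changed it made 0.05 calls on average. The simulated errors were normal, with 1 spread per gene shared by all arrays. In the real data, limma's array weights ran from 0.176 (KO replicate 1) to 3.32 (WT replicate 2). The median size of change among genes past the threshold was 0.35, below both simulated sizes, so these rates need not hold for the real arrays. A list shifted by 0.2 was called in all 20 simulations, with independent errors between genes, which real lists do not have.

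The alternatives were another quantile normalization, centring on the array median, no filter and a stricter filter at the 50th percentile, an intensity trend with a robust prior, array weights, the mean over a gene's probe sets, all probe sets, the replicate number as a block, each array left out in turn, thresholds of 0.01 and 0.1, and for lists an estimated correlation and the rotation test fry. Leaving out KO replicate 1 and WT replicate 3 together was added after the data were seen.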

Results

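Bcl6 is a transcriptional repressor required for the follicular helper T (Tfh) cell fate, and the comparison asks which transcripts depend on it when naive CD4 T cells are activated under Tfh-promoting conditions. Expression was compared between 4 WT-labelled and 4 KO-labelled arrays after 24 hours of culture. Arrays correlated with one another at r between 0.986 and 0.998 across tested genes, and no pair shared more than 3.4% of its values exactly. Xist stood between 12.4 and 12.8 and the Y-linked Eif2s3y between 3.67 and 3.80 in all 8 arrays, so the groups did not differ in these sex-linked transcripts. KO replicate 1 stood apart from the other KO-labelled arrays: its deviations from the group were larger (median 0.153 on the log2 scale, against 0.0533 to 0.0967 in the other 3), and the array most correlated with it was WT replicate 3.

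Bcl6 itself was higher, not lower, in the KO-labelled arrays. Its log2 signal was 8.77 ± 0.123 (SD, n = 4) in the WT-labelled arrays and 9.15 ± 0.0497 (SD, n = 4) in the KO-labelled arrays, a log2 difference of 0.38 ± 0.0645 (SE; limma adjusted p = 0.0303, exact permutation p = 0.0286, the smallest 4 against 4 can give). All 4 KO-labelled values, 9.08 to 9.19, lay above all 4 WT-labelled values, 8.61 to 8.91. A single probe set is named for the gene in the probe table used, and where it lies relative to the deleted exons is not known here, so it does not check the labels. Directions below are therefore those of the arrays as labelled. The call for Bcl6 was lost (limma adjusted p of 0.0591 to 0.11) without WT replicate 3 or 4 or without KO replicate 2, 3 or 4, while the difference stayed between 0.32 and 0.42 in all 8 such fits.

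**Figure D1:**
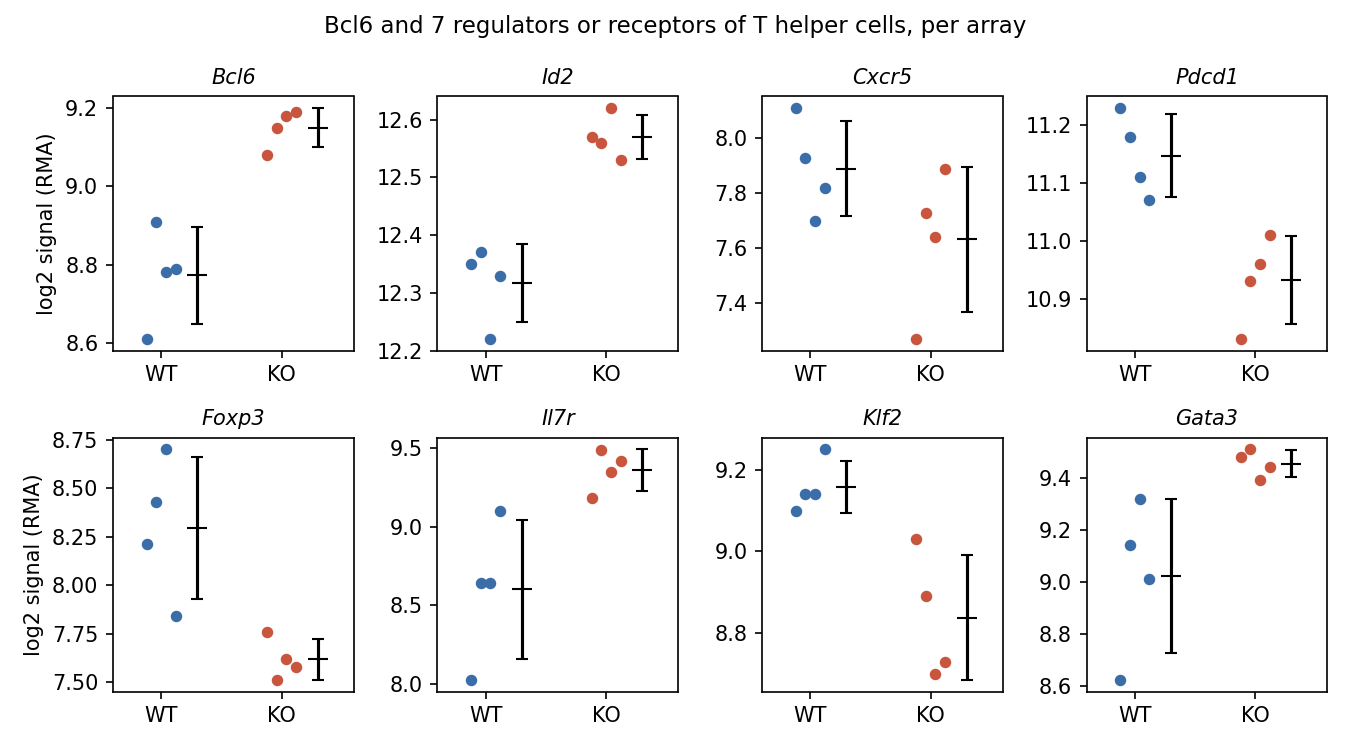
Log2 signal (vertical axis) of Bcl6 and 7 other always-named genes in each WT-labelled (blue) and KO-labelled (red) array, in order of replicate number; black marks are the mean and SD of 4 arrays, and the vertical axes differ between panels and do not start at 0. Bcl6 lies between 9.08 and 9.19 in the KO-labelled arrays and between 8.61 and 8.91 in the WT-labelled arrays.

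The largest rises in the KO-labelled arrays were in F3, the tissue factor that starts blood coagulation, and F2rl2, a receptor of the thrombin receptor family. F3 rose 2.62-fold, from 7.25 ± 0.259 to 8.64 ± 0.344 (log2, SD, n = 4, limma adjusted p = 0.00728), and F2rl2 rose 2.48-fold, from 7.70 ± 0.0876 to 9.01 ± 0.147 (limma adjusted p = 4.89e-05). Neb, which encodes the muscle filament protein nebulin, rose 2.33-fold and Lipg, an endothelial lipase, 2.24-fold. Il3, a haematopoietic cytokine made by activated T cells, rose 2.13-fold (limma adjusted p = 0.0226) from a level under the expression filter in 2 of the 4 WT-labelled arrays, and Ajuba, a LIM-domain adaptor protein, 2.01-fold. Lpp, the tested gene next to Bcl6 on chromosome 16, had the smallest p of all genes: it rose from 10.2 ± 0.0759 to 11.2 ± 0.0183 (2.08-fold, limma adjusted p = 1.53e-05), and all 3 of its probe sets were higher. B4galt4, a galactosyltransferase, rose 1.83-fold, Nrn1, which encodes neuritin, 1.84-fold, and the histone gene H3c15 2.02-fold. F3 and H3c15 each lay under the filter in 1 WT-labelled array.

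The largest fall was in Cd96, an immunoglobulin-family receptor of T and NK cells, which went from 9.55 ± 0.251 to 8.43 ± 0.235 (log2, SD, n = 4; a difference of -1.12 ± 0.14, SE, limma adjusted p = 0.00728). Cldn10, a tight-junction claudin, fell by 0.91 on the log2 scale, to values that lay under the expression filter in all 4 KO-labelled arrays. Gpr83, a receptor abundant in regulatory T cells, fell by 0.63 (10.9 ± 0.0896 to 10.3 ± 0.104, limma adjusted p = 0.00333), and Cemip2, a cell-surface hyaluronidase, also fell by 0.63. Tmem267 fell by 0.67, the adhesion molecule Epcam by 0.57, Ifi27l2a, an interferon-induced gene, by 0.56, the junction protein gene Jup by 0.53, Eng, which encodes the TGF beta co-receptor endoglin, by 0.51 and the epoxide hydrolase Ephx1 by 0.50. F3, F2rl2, Neb, Lipg, Lpp, Ajuba, Nrn1, B4galt4, Cd96, Cldn10, Cemip2, Gpr83, Jup, Ephx1 and Dapl1 passed the threshold in every fit that left 1 array out. Il3, H3c15, Tmem267, Epcam, Ifi27l2a and Eng did not, with limma adjusted p reaching 0.093, 0.146, 0.117, 0.0844, 0.164 and 0.0844.

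In all, 157 of 11926 genes passed the threshold, 77 higher and 80 lower in the KO-labelled arrays, and 1980 genes had an unadjusted p under 0.05 where 596 are expected with no effect. The changes were small: the median size among the 157 was 0.35 on the log2 scale, 25 genes changed at least 1.5-fold (20 higher, 5 lower) and 9 at least 2-fold (8 higher, Cd96 lower). The groups did not overlap in any of the 157 genes, nor in 10.8% of all tested genes, against 2.86% by chance. Of the 157, 14 had more than 1 probe set, and 2 of these had a probe set, of whatever level, with a change of the opposite sign. The count of 157 depended on single arrays. It was 782 without KO replicate 1 and 32, 34 and 68 without KO replicate 2, 3 and 4. Without WT replicate 1, 2, 3 and 4 it was 74, 31, 34 and 107. With each array centred on its median, 48 genes were higher and 30 lower. Of the 34 named genes past the threshold other than Bcl6, all 34 passed without KO replicate 1, while 19, mostly members of the lists below, were lost when at least 1 other array was left out.

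**Figure D2:**
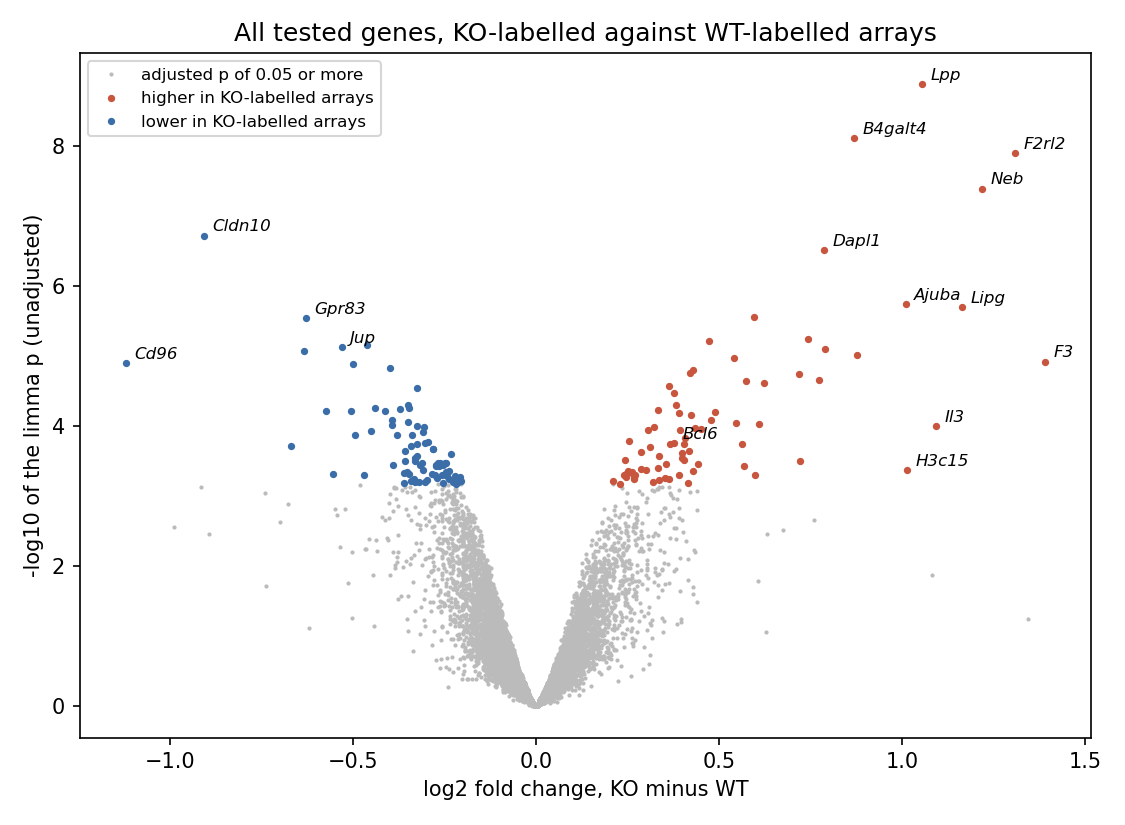
Log2 fold change, KO minus WT (horizontal axis), against -log10 of the unadjusted limma p (vertical axis) for the 11926 tested genes; red and blue points are the 77 genes higher and the 80 genes lower in the KO-labelled arrays at an adjusted p under 0.05. Lpp has the smallest p, and F3 and Cd96 have the largest rise and fall among genes past the threshold.

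Of the always-named regulators, receptors and cytokines given here, Id2 alone passed the threshold beside Bcl6. Id2, an inhibitor of E-protein transcription factors, rose from 12.3 ± 0.067 to 12.6 ± 0.0374 (log2, SD, n = 4, limma adjusted p = 0.0462), a call kept only without KO replicate 1 among the fits with 1 array left out (adjusted p of 0.0203 there and up to 0.142 in the other 7). Il7r, the IL-7 receptor chain, differed by 0.76 ± 0.185 (SE, limma adjusted p = 0.0794), Foxp3, the regulator of regulatory T cells, by -0.68 ± 0.153 (adjusted p = 0.0648), Gata3 by 0.43 ± 0.124 (adjusted p = 0.118), Klf2 by -0.32 ± 0.0753 (adjusted p = 0.0756) and the inhibitory receptor gene Pdcd1 by -0.21 ± 0.0559 (adjusted p = 0.0931). The groups did not overlap in these 5 genes, nor in Il21 and Batf, yet none of them passed over the 8 arrays. Without KO replicate 1, Klf2 (limma adjusted p = 0.00848), Foxp3 (0.0304) and Il7r (0.0381) passed, and without WT replicate 4 Foxp3 (0.0191) and Il7r (0.0355). The chemokine receptor gene Cxcr5 differed by -0.26 ± 0.129 (limma adjusted p = 0.361), Il21 by 0.11 ± 0.0484 (0.268), Tbx21 by -0.10 ± 0.0613 (0.447), Selplg by -0.11 ± 0.0513 (0.31) and Batf by -0.08 ± 0.0402 (0.346). Icos, Gpr183 and Maf differed by no more than 0.05 on the log2 scale, with limma adjusted p from 0.675 to 0.914. Prdm1, the gene of the repressor Blimp1, lay under the expression filter in all 8 arrays (6.71 ± 0.119 against 6.83 ± 0.0818, exact permutation p = 0.143) and was not tested further.

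The Tfh list did not pass (mean -0.04, camera adjusted p = 0.627). Of its 22 tested members, Cd200, an immunoglobulin-family glycoprotein, rose by 0.34 (limma adjusted p = 0.038), Tox, a nuclear factor, fell by 0.39 (0.0423) and 20 did not pass; adjusted over the list alone, 1 was higher and 4 lower. Both calls were lost in most fits that left 1 array out, with adjusted p up to 0.143 and 0.146, whereas without KO replicate 1 the calls numbered 3 higher and 5 lower, and without WT replicate 4, 0 and 2. Known targets of repression by Bcl6, taken from the literature, did not pass as a list either: 1 of 24, Id2, rose, with a mean of 0.03, a median of -0.01 and a camera adjusted p of 0.459. Adjusted over the list alone, 3 of the 24 were higher and 2 lower. Without KO replicate 1, 2 were higher and 3 lower over all genes (camera adjusted p of the list 0.818), with Klf2 among the lower; the other 7 fits with 1 array left out called at most 1.

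Among cytokine and lineage genes the calls were scattered. Il12rb2, a chain of the IL-12 receptor, rose by 0.72 (limma adjusted p = 0.0418) and was the only call among 20 Th1 genes. Il3 was the only call among 11 Th2 genes, and Nfkbiz, a nuclear NF-kappa-B regulator, which fell by 0.36 (limma adjusted p = 0.0495), the only call among 10 Th17 genes. Gpr83 was the only call among 18 regulatory T cell genes, a list whose mean (-0.12) and median (0.04) differed in sign (camera adjusted p = 0.911). Adjusted over the list alone, 1 Th1, 3 Th2, 1 Th17 and 0 regulatory T cell genes were higher, and 3, 1, 2 and 5 were lower. Il6ra, the IL-6 receptor, fell by 0.33 (limma adjusted p = 0.0226), alone among 30 cytokine receptor and JAK-STAT genes; 2 were higher and 8 lower adjusted over the list alone. Dapl1, 1 of 22 naive and memory precursor genes, rose 1.73-fold (11.1 ± 0.106 to 11.9 ± 0.0819, limma adjusted p = 0.000598), and adjusted over the list alone 2 were higher and 5 lower. The camera adjusted p of these 6 lists lay between 0.171 and 0.911. Without KO replicate 1 the calls over all genes numbered 1 higher and 1 lower (Th1), 2 and 1 (Th2), 0 and 3 (Th17), 1 and 3 (regulatory T cells), 1 and 4 (cytokine receptors) and 2 and 2 (naive and memory precursors).

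Replication-dependent histone genes were higher as a group in the KO-labelled arrays: 20 of 22 had a positive difference, with a mean of 0.22 (camera adjusted p = 5.36e-11). The list's adjusted p was 0.385 with an estimated correlation. H3c15 alone passed over all genes, and 14 were higher and 1 lower adjusted over the list alone. The list mean was 10.2 ± 0.0604 in the WT-labelled and 10.4 ± 0.0806 in the KO-labelled arrays (SD, n = 4), with no overlap. Cell cycle genes were likewise higher (28 of 38 positive, mean 0.10, camera adjusted p = 1.55e-06; adjusted p = 0.851 with an estimated correlation). The mitotic genes Nusap1, a spindle protein, and Cenpe, a kinetochore motor, rose by 0.49 and 0.43 (limma adjusted p = 0.0182 and 0.0462), whereas Cdt1, which licenses replication origins, fell by 0.26 (0.0423); 15 were higher and 1 lower adjusted over the list alone. Over all genes, 13 cell cycle genes were higher and 1 lower without KO replicate 1, and 4 histone genes were higher, while each of the other 7 fits called at most 1 gene of either list. The mean of the cell cycle list in KO replicate 1, 11.3, lay at the level of the WT-labelled arrays.

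Genes of T cell receptor signalling and the early activation response were lower as a group (20 of 27 negative, mean -0.10, camera adjusted p = 0.0135; adjusted p = 0.851 with an estimated correlation). Nfatc1, the calcium-dependent transcription factor, fell by 0.24 (limma adjusted p = 0.0489), and 1 was higher and 8 lower adjusted over the list alone. The call of the list was lost without KO replicate 1 (adjusted p = 0.106) and without WT replicate 2 (0.0946). No list passed with an estimated correlation or with fry. At the preset correlation, 28 of the 35 ways to split the 8 arrays into 4 and 4 gave at least as many lists. The count of 3 lists is thus not distinguished from differences between any arrays. The splits were not compared list by list, so they do not decide on a single list.

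**Figure D3:**
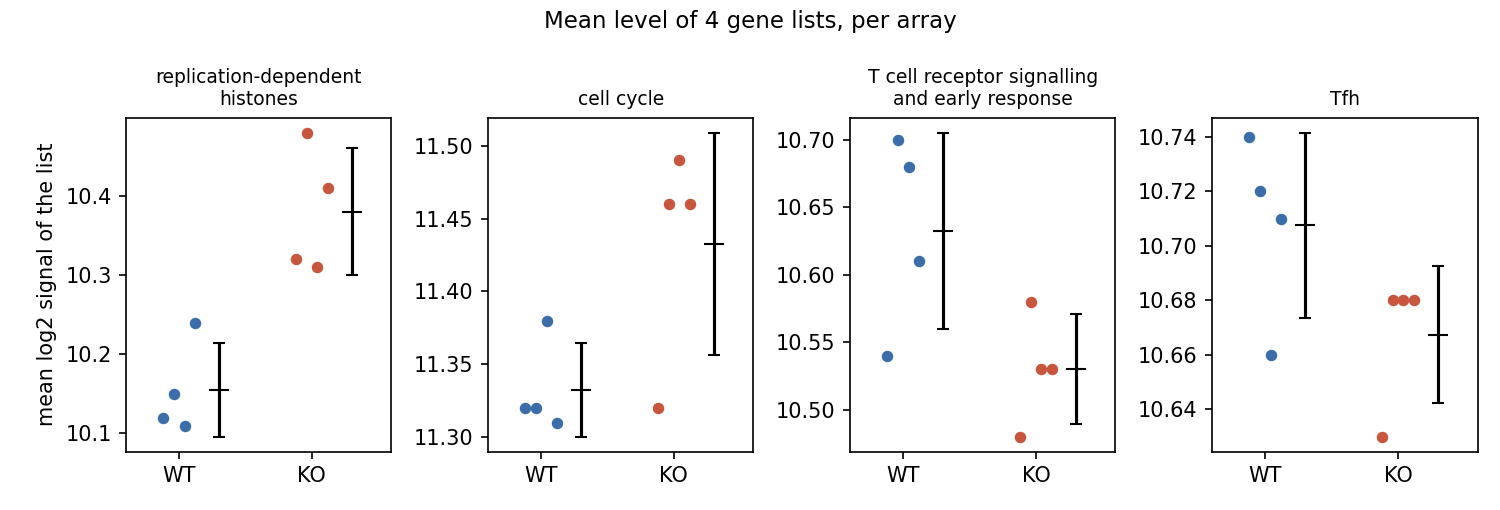
Mean log2 signal (vertical axis) of 4 gene lists in each WT-labelled (blue) and KO-labelled (red) array, in order of replicate number; black marks are the mean and SD of 4 arrays, and the vertical axes differ between panels and do not start at 0. The histone list has no overlap between the groups, and KO replicate 1 lies at 11.3 in the cell cycle panel, with the WT-labelled arrays.

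Other fixed lists held few calls. Zbp1, a sensor of nucleic acids, rose by 0.34 (limma adjusted p = 0.0181), alone among 25 interferon response genes (camera adjusted p = 0.0551; 4 higher and 2 lower adjusted over the list alone). Fdft1, which encodes squalene synthase, rose by 0.27 (limma adjusted p = 0.0467), alone among 19 cholesterol synthesis genes, and Trp53inp1, a p53-induced gene, fell by 0.39 (limma adjusted p = 0.0216), alone among 19 genes of p53 and apoptosis; their camera adjusted p were 0.171 and 0.911, with 1 and 1 higher and 0 and 1 lower adjusted over the list alone. No gene passed among 20 glycolysis genes, 55 ribosomal protein genes, 48 small nucleolar RNAs, 20 trafficking receptor and adhesion genes or 18 T cell identity genes (camera adjusted p from 0.107 to 0.987). The members with the smallest p were Pfkfb3 (-0.19, limma adjusted p = 0.151), Rps29 (-0.25, 0.0507), Snora73a (-0.24, 0.121), Ccr4 (0.28, 0.0689) and Skap1 (-0.18, 0.0794). Adjusted over the list alone, 1 trafficking gene was higher, and 3 trafficking genes, 1 ribosomal protein gene and 1 T cell identity gene were lower. Over all genes and without KO replicate 1, 4 interferon response, 3 cholesterol synthesis, 2 p53 and apoptosis and 1 trafficking genes were higher, and 4 ribosomal protein, 2 trafficking, 1 p53 and apoptosis and 1 T cell identity genes lower.

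Markers of B, myeloid and erythroid cells that the sort could have let through were mostly under the expression filter. So were cytotoxic and NK genes (6 of 24 on the array tested), but not CD8 T cell genes (5 of 6 tested). Of 18 B cell, 22 myeloid and 4 erythroid genes on the array, 4, 4 and 1 could be tested, and none passed; Ighm (0.14, limma adjusted p = 0.561), Cst3 (-0.16, 0.118) and Slc4a1 (-0.07, 0.762) had the smallest p. Adjusted over the list alone, 1 myeloid gene was lower. None of 5 tested CD8 T cell and 6 cytotoxic and NK genes passed over all genes (camera adjusted p = 0.113 and 0.107), whereas 3 and 4 were lower adjusted over the list alone; Crtam, a CD8 and NK cell receptor, differed by -0.54 (limma adjusted p = 0.0764) and the protease gene Ctsw by -0.52 (0.0696). Crtam passed without KO replicate 1 (0.0199) and Ctsw without WT replicate 4 (0.0244).

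The genes nearest to Bcl6 in chromosome order were examined because a targeted allele can carry flanking sequence of another strain. Of the 10 tested genes on either side, Lpp alone passed (5% of 20 genes, against 1.29% of the 11898 others; Fisher's exact p = 0.23, two-sided). Over the whole of chromosome 16, a comparison added after the data were seen, 17 of 365 genes passed (4.66%), against 1.2% of the genes elsewhere (Fisher's exact p = 5.69e-06, 0.000114 after adjustment over 20 chromosomes). B4galt4, Cd96, Cd200 and Nfkbiz are among these 17. Fisher's test takes genes as independent, which genes measured on the same arrays need not be, so its p-values here may overstate the evidence. The odds ratio, 4.01 over all 8 arrays, was 1.64 without KO replicate 1 (10.1% against 6.44%, Fisher's exact p = 0.00941), 2.53 without KO replicate 4 (1.37% against 0.545%, p = 0.057), 2.59 without WT replicate 4 (p = 0.0169) and 7.7 without WT replicate 2 (p = 0.000304), and lay between 3.9 and 6.88 without each of the other 4 arrays.

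**Figure D4:**
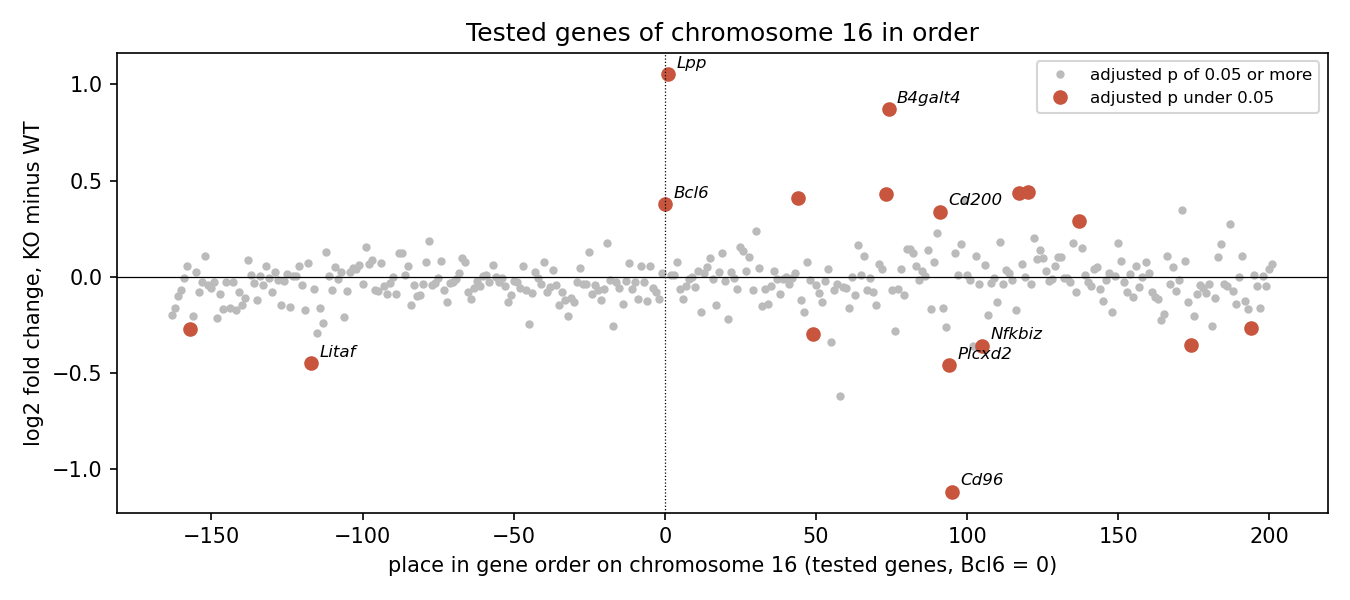
Log2 fold change, KO minus WT (vertical axis), of the tested genes of chromosome 16 in order along the chromosome, with Bcl6 at 0 on the horizontal axis; red points are the 17 genes with an adjusted p under 0.05. 14 of the 17 follow Bcl6 in this order, among them Lpp, B4galt4 and Cd96, and 2 precede it.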

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

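The tests of the Bcl6 direction, of chromosome 16 and of the label of KO replicate 1 were chosen after the results they bear on were seen; the counts over splits of the arrays and the test of signal range were set before.

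In 12 of 160 groups of 4 values, for named genes and list means, 1 array lay far from the other 3; chance alone gives about 8. In WT replicate 1, F2rl2 (7.57, the others 7.73 to 7.76), Lipg (7.83) and Ajuba (7.69) were low, as were the means of the cytokine receptor list (10.76, the others up to 10.97) and of the literature targets of Bcl6 (10.48). In KO replicate 1, H3c15 (7.39, the others 8.24 to 8.4), Cd200 (12.12) and the mean of the Tfh list (10.63) were low. Rps29 was low in WT replicate 4 (12.73) and in KO replicate 3 (12.49), Skap1 was low in KO replicate 3 (10.22), and the T cell identity list was high in KO replicate 2 (11.87).

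Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many as 157 changed genes. The highest of the others gave 1. A random grouping of the arrays is thus an unlikely source of this count, though 1 of 35 is the smallest share this test can give. The test does not bear on single genes or on other differences that go with the groups. The same holds for the 25 genes changed at least 1.5-fold, reached by 1 of 35 splits, with 1 as the highest of the others. Chance cannot be excluded for the count of 3 gene lists past the threshold: 28 of the 35 splits gave as many, and another split gave 10.

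Bcl6 was higher in the KO-labelled arrays. If the labels of the groups were exchanged, known targets of Bcl6 repression would be lower in the KO-labelled arrays, and the list passed in neither direction (camera adjusted p = 0.459; 0.818 without KO replicate 1, where 2 of its genes were called higher and 3 lower), so an exchange cannot be told apart from correct labels by this list. A transcript that keeps the probed part of the gene, with loss of the repression that Bcl6 is known to exert on its own gene, may also give a rise, but only 1 probe set is named for Bcl6 in the probe table used, which does not list 12146 of the 35556 probe sets, so no second one could be set against it. Both stay open.

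Calls were concentrated on chromosome 16. The region of Bcl6 and Lpp alone does not account for it, since without both genes 15 of 363 genes passed there, 4.13% against 1.2% elsewhere (Fisher's exact p = 7.1e-05). Flanking sequence of another strain, carried with the targeted allele, is a candidate explanation that stays open. Of 200 genes within 100 on either side of Bcl6, 8 were called (Fisher's exact p = 0.0046), and 1.58% of windows centred on other genes held as many. These windows overlap, and those on chromosome 16 share the same calls, so the 1.58% is not a p-value. The Fisher's exact p-values take genes as independent, which genes measured on the same arrays need not be. All 8 calls follow Bcl6 in gene order, so the excess does not centre on it. The 2 called genes that precede Bcl6 lie outside this window. Nearer to Bcl6 no excess was detected, with 3 of 100 within 50 genes on either side (Fisher's exact p = 0.141), 1 of 50 within 25 (0.481) and 1 of 20 within 10; the widths other than 10 were added after the data were seen, a window on another chromosome also held 8, and the strain of the mice is not given in the sources used here. An effect of Bcl6 itself on these genes was not tested and stays open.

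KO replicate 1 stood apart from the other KO-labelled arrays. A narrower signal range in that array is consistent with the data: its deviations correlated with the level of the gene across genes at r = -0.355, against -0.125 to 0.285 in the other 7 arrays. Single genes argue against a WT array with a wrong label: Lpp was 11.21 in this array, against 10.08 to 10.25 in the WT arrays and 11.22 to 11.25 in the other KO arrays, B4galt4 was 8.33 against at most 7.57 in WT, and Cldn10 6.70 against at least 7.42. Over the 50 genes with the smallest p without this array, neither test reached its bound. In the first test, 34 had it nearer to the other KO arrays, where 45 would have excluded a WT array. WT arrays left out in the same way gave 0 to 15, the other KO arrays 44 to 48. The second test was added once the 34 was known. In it, 27 genes had this array beyond all WT arrays by more than their range, where more than 37.8 was needed. WT arrays gave 1 to 20, the other KO arrays 41 to 46. Each left-out WT array was measured against the remaining WT arrays only, and each KO array against all of them, whose range is wider or equal. The WT counts and the bound drawn from them are thus not like for like with the 27, so the second test cannot decide. By the first test, KO replicate 1 lay between the groups over these 50 genes, which did not exclude a wrong label. The main axes of variation between arrays (principal components) placed it differently. On the second (26.54% of variance) it lay at -10.07, the other KO arrays at -6.177 to -4.219 and the WT arrays at 5.497 to 7.994, which argues against a WT array. On the first (41.63%) it lay at -16.59, outside both groups. It was beyond the lowest of the WT arrays (-6.999 to 3.59) and still farther from the other KO arrays (4.677 to 12.83). This axis therefore places it with neither group. A difference between mice was not tested.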

How the results depend on the processing

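Leaving out KO replicate 1 and WT replicate 3 together was chosen after the data were seen; the other alternatives were fixed before. None of the 34 named genes past the threshold changed sign in any alternative; 15 of them passed in each fit with 1 array left out, and 13 in every alternative. Of 23 named genes not past it, 14 passed in at least 1 alternative, and 8 with 1 array left out (7 of them without KO replicate 1). Maf, near 0, ranged from -0.05333 to 0.01333 with 1 array left out (0.01083 without WT replicate 2, 0.01333 without KO replicate 4). Fewer arrays lower the power of a fit, which is part of the lost calls; the cause of other changes was not tested. Dim genes limit the lists of other cell types.

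Changed genes (157, 77 higher, 80 lower) numbered 322 (173 higher, 149 lower) after quantile normalization, 78 (48, 30) with arrays centred on their median, 58 (37, 21) with no filter, 354 (151, 203) with an intensity trend and robust prior, 1980 (1010, 970) with array weights, where KO replicate 1 had a weight of 0.176, 443 (293, 150) without KO replicate 1 and WT replicate 3, 44 (29, 15) over all probe sets, 27 (19, 8) at a threshold of 0.01 and 468 (182, 286) at 0.1. The stricter filter gave 139 lower. With 1 array left out the counts ran from 31 to 782, 22 to 463 higher and 9 to 319 lower; those changed at least 1.5-fold ran from 18 to 38, and were 53 with array weights.

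The evidence for pairing by replicate number was mixed: deviations of same-numbered arrays correlated at 0.0111, 0.145, -0.174 and 0.308. Arrays 2 and 4 correlated best with their own number, and arrays 1 and 3 did not. With the replicate block 36 genes passed (25 higher, 11 lower), Bcl6 (0.3775) had an adjusted p of 0.0606, and the interferon list (0.0756) passed.

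Bcl6 (0.3775) also lost its call with no filter (adjusted p = 0.0595, from 0.00507 to 0.11 over all alternatives), and ranged from 0.3233 to 0.4233 with 1 array left out. The share of called genes near Bcl6 was 5% throughout these fits, past the threshold without WT replicate 2, and below the share elsewhere with array weights (5%) and without KO replicate 1.

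Lists past the threshold numbered 5 with median centring, 5 with no filter, 0 with an estimated correlation, 0 with fry and 3 to 8 with 1 array left out. Means of lists are given on the log2 scale. The histone (0.2215), cell cycle (0.1039) and early response (-0.1037) lists lost their calls with an estimated correlation and with fry; the early response list also did so without KO replicate 1 and WT replicate 3 (-0.07284) and ranged from -0.1356 to -0.08 with 1 array left out. These lists became called: ribosomal proteins after quantile normalization (-0.05509), with no filter (-0.05246), with the trend (-0.05427) and without KO replicate 1 and WT replicate 3 (-0.06873); cytotoxic genes with median centring (-0.32) and the stricter filter (-0.409); interferon response with median centring (0.0856) and the mean over probe sets (0.0795); CD8 T cells with no filter (-0.1962); cholesterol synthesis with array weights (0.07716) and without KO replicate 1 and WT replicate 3 (0.08263). With 1 array left out, further lists became called: CD8 T cells (adjusted p = 0.0259), cytokine receptor (0.00284), cytotoxic (0.0284), naive and memory precursor (0.0259) and trafficking (0.0305) without WT replicate 1, interferon response without WT replicate 2 (0.00795), WT replicate 4 (0.0172) or KO replicate 3 (0.0291), ribosomal proteins without WT replicate 3 (0.00323), cytotoxic (0.0225) and small nucleolar RNAs (0.00215) without WT replicate 4, and cholesterol synthesis without KO replicate 1 (0.0423). Uncalled lists near 0 turned sign: T cell identity after quantile normalization (0.002622), median centring (0.007222) and without KO replicate 1 and WT replicate 3 (0.001111), which also turned p53 and apoptosis (0.0214), small nucleolar RNAs (0.003819) and Th1 (0.0445); Th2 with the stricter filter (-0.05906) and glycolysis with array weights (0.01518).

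With 1 array left out, list means ran from -0.2783 to -0.161 (CD8 T cells), -0.09294 to -0.02506 (cytokine receptor), -0.4086 to -0.2542 (cytotoxic), -0.01215 to 0.0516 (literature targets), -0.0608 to -0.005038 (naive and memory precursor), -0.1221 to 0.03316 (small nucleolar RNAs), -0.1108 to -0.05329 (trafficking), 0.04217 to 0.1068 (interferon), -0.01259 to 0.002222 (T cell identity), -0.08858 to 0.01908 (Th1), -0.07253 to -0.03847 (ribosomal proteins), 0.01211 to 0.0814 (cholesterol synthesis) and -0.04127 to 0.009605 (p53 and apoptosis).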

Other observations

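The genes and the test in this part were chosen after their values were seen. F2r, the thrombin receptor gene, rose by 0.79 on the log2 scale in the KO-labelled arrays (limma adjusted p = 0.00617), beside F3 and F2rl2. Sgo2a, which protects centromere cohesion, rose by 0.48 (limma adjusted p = 0.0216), and the kinetochore scaffold gene Knl1 by 0.41 (0.0415), as single genes with no test of a group. The stress-induced transcription factor gene Atf3 rose by 0.77 (limma adjusted p = 0.0099), and Ikzf3, which encodes the lymphoid factor Aiolos, fell by 0.47 (0.0467). Each of these genes, like all 157 past the threshold, had no overlap between the 4 KO-labelled and 4 WT-labelled arrays.

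Ndufa4, Ndufb6 and Atp5mpl, which encode subunits of the mitochondrial respiratory chain and ATP synthase, fell by 0.33, 0.32 and 0.34 (limma adjusted p = 0.0415, 0.0423 and 0.0258). A shift of the group was tested as a hypothesis on 90 tested genes chosen by symbol (Nduf, Atp5, Cox4 to Cox8, Uqcr and Sdh), which need not all be subunits. It was not found in this set: 52 were below 0 and 38 above, with a mean of -0.04 and a camera p of 0.137 at the preset correlation (p = 0.547 with an estimated correlation).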
